A study of Danio rerio with 3 samples.

How the data were processed

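Single-cell RNA-seq was measured in 3 libraries of zebrafish larvae, 1 at each of 3, 5 and 7 days post fertilization (dpf). The larvae carried the Tg(olig2:EGFP) transgene, in which regulatory sequence of olig2 drives a green fluorescent protein. Olig2 is the transcription factor of the pMN domain, the ventral spinal cord progenitor domain that gives rise to motor neurons and then to oligodendrocyte lineage cells. Per the labels' protocols, larvae were deyolked and dissociated with a protease on ice, EGFP-positive cells were taken by fluorescence-activated sorting, and droplets were made with a 10x Chromium 3' kit and sequenced on an Illumina NovaSeq. That description names no dissection of the spinal cord, so cells outside the spinal cord with reporter signal could enter the sort.

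The deposited matrices hold whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, made with Cell Ranger 5.0.1 per the file headers. The genome build was GRCz11, and Seurat 4.1.0 was also used with no role given, per the submitters' processing notes. The annotation release is not given in the sources used here. Each matrix has 25109 rows, among them a GFP and an mCherry row added to the genes. No deposited barcode had under 500 UMIs. Gene names were taken as the deposited files pair them with Ensembl identifiers. Among the symbols, 515 belong to more than 1 row, and such rows were kept apart by their identifier. Counts of near-identical paralogs such as the her4 genes can be split between copies and are uncertain per copy. A 3' kit also reads mainly transcript ends.

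Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs (13 mitochondrial genes). This removed 15 barcodes for few genes and 20 for their mitochondrial share. Scrublet in scanpy 1.11.5 was run on each library, with an expected doublet rate of 0.8% per 1000 cells, and its calls were removed. It called 23 of 8296 cells (0.277%), fewer than the expected 153, 36 and 26 at 3, 5 and 7 dpf. The sources used here do not say whether doublets were removed before deposit, so the number left among the 8273 cells used is unknown. As an alternative chosen after seeing the data, the expected numbers of cells with the highest scores were removed instead. Counts were scaled to 10000 per cell and log-transformed. Clusters were made on all 3 libraries together from 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1.0 and no batch integration, because library and age are the same variable. The 282 genes of the readout lists, mitochondrial genes, 87 ribosomal protein genes and the reporter rows were left out of the variable genes.

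Marker lists for 25 cell types and 15 readout lists (493 symbols, of which 485 were found) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. A cluster took the name of the list with the highest mean log2 fold over all other cells (20 CPM added to each side), if at least 3 of its markers exceeded 2-fold. A cluster stayed unnamed where its 10 leading genes, among genes at 100 CPM or more, held at least 1 marker of another class, and as many or more markers of all other classes together as of its own class. This last condition was set after the clusters were seen; as first written, a cluster stayed unnamed only where they held more markers of 1 other class. It kept 2 more clusters unnamed. Cluster 19, first called erythroid-like, held 1.81%, 2.79% and 1.34% of cells at 3, 5 and 7 dpf, and cluster 24, first called Schwann/neural-crest-like, held 0%, 0.0472% and 3.97%. Every result was also computed with the rule as first written.

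With 1 library per age there is no test between ages. Levels are given as CPM, a gene's UMIs summed over cells and scaled by those of all genes, with exact 95% Poisson intervals. Ratios of 7 to 3 dpf have exact conditional binomial intervals, and shares of cells have exact (Clopper-Pearson) binomial intervals. Ratios of shares have an approximate log-scale interval. All of these cover counting error only, not differences between larvae, dissociations or sorts. A ratio against 0 UMIs is given as a bound against a floor of 3 UMIs in the class at that age. A share of 0 is given with the limit of 3 cells over those counted. A readout list's median log2 ratio (1 CPM added, members at a mean of 10 CPM or more) was placed as a percentile among 10000 random lists of the same size matched on expression in 20 bins. Its interval covers 95% of 1000 Poisson redraws of the counts. Within-class age ratios were made for classes with at least 50 cells at both 3 and 7 dpf. Genes named there were the 8 most higher and 8 most lower in progenitor-like, OPC-like (oligodendrocyte precursor) and oligodendrocyte-like cells, by the interval end nearest to 1, at 50 CPM or more in the higher library. Mitochondrial and ribosomal protein genes and markers of erythroid, muscle, epidermal, gut, lens and leukocyte cells were left out. Shares of cells with a UMI, and of proliferating cells (at least 2 UMIs over the G2/M list), were made after thinning each cell to 1000 UMIs and leaving out shallower cells, 649, 496 and 218 of them at 3, 5 and 7 dpf.

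For contrasts between classes, counts were summed per library and class where the class had at least 30 cells. The 9 sums of progenitor-like, OPC-like and oligodendrocyte-like cells entered 1 edgeR 4.0.16 quasi-likelihood fit with TMM scaling, filterByExpr and the library as a block. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and list counts were also adjusted over the list alone. They measure only the spread between these sums, each library being 1 preparation. Standard errors (SE) are the log2 fold divided by the square root of the F statistic. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. Named were the 3 members of each readout list with the smallest p, the member with the highest mean expression, and olig2, sox2, sox10, mbpa and the reporter. Genes of the marker lists and genes used for clustering were not reported as findings of a contrast.

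Both pipelines were tested on simulated counts. Among genes given a log2 change of 1, the fit recovered 5.26% for oligodendrocyte-like against OPC-like (9261 genes run) and 5.88% for progenitor-like against OPC-like (8699 genes run). For a log2 change of 2 it recovered 64.9% and 62.2%. Few genes were changed in each simulation, whereas 2830 and 3339 of 10237 genes passed in the real contrasts. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the power of the real contrasts. False calls were 2 (2.94% of calls) and 0. The age intervals covered 95% to 97% of the simulated changes in progenitor-like, oligodendrocyte-like and neuron-like cells (25109 rows run). Those counts were Poisson draws, which the intervals assume. The coverage therefore checks the computation only, not the spread between cells or libraries.

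The alternatives were a cell filter of 1000 UMIs, a mitochondrial limit of 10%, doublets kept, Leiden resolutions of 0.5 and 2.0, readout genes kept in clustering, each library clustered alone, neural classes as the denominator, all deposited barcodes, CPM without mitochondrial, ribosomal protein and erythroid genes, TMM sizes, thinning before summing, other UMI minimums for proliferation, DESeq2 1.42.0, no expression filter, no library block, and each library left out in turn. Chosen after seeing the data were the expected doublets removed, the naming rule as first written, and the progenitor-like class without the cluster that held most of it at 7 dpf and, for age ratios, at 3 dpf. Genome coordinates were not used here.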

Results

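The study sampled the olig2 lineage of zebrafish larvae at 3, 5 and 7 dpf, ages at which pMN-derived oligodendrocyte precursors divide, differentiate and begin to myelinate. Each age was 1 library of sorted EGFP-positive cells. The 3 dpf library held 4376 barcodes and 12083308 UMIs, with a median of 2189 UMIs per barcode. The 5 dpf library held 2128 barcodes and 5118316 UMIs, with a median of 1688, and the 7 dpf library 1827 barcodes and 7164416 UMIs, with a median of 2774. After filtering, 4367, 2118 and 1788 cells were used. The median mitochondrial share was 0.693%, 0.95% and 1.28% at 3, 5 and 7 dpf. Because each age was 1 library, differences between ages have no replicate check, and age cannot be separated from the day of dissociation, sort or capture.

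Over all cells of a library, transcripts of the reporter and of the lineage were present at every age. The reporter was at 1326 CPM at 3 dpf, 1213 at 5 dpf and 970 at 7 dpf, a 7 to 3 dpf ratio of 0.731 (95% interval 0.711 to 0.752). Olig2 was at 513, 628 and 711 CPM, a ratio of 1.39 (1.33 to 1.44), and sox10, a transcription factor of oligodendrocyte and neural crest lineages, at 428, 269 and 330 CPM, a ratio of 0.771 (0.734 to 0.810). Sox2, a progenitor transcription factor, was at 186, 320 and 150 CPM (ratio 0.808, 0.750 to 0.869). The myelin genes went different ways. Plp1b was 2.50-fold higher at 7 than at 3 dpf (2.43 to 2.58) and mbpa 1.28-fold (1.25 to 1.3), whereas mbpb had a ratio of 0.388 (0.382 to 0.393). After thinning to 1000 UMIs, a reporter UMI was found in 23.3% of cells at 3 dpf, 48.2% at 5 dpf and 32.4% at 7 dpf (26.5%, 48.8% and 41.8% unthinned). Epidermis-like cells, which should lack the reporter, had one in 1 of 14 cells (7.14%, 0.181% to 33.9%; 18.8% unthinned), too few to set a background, and neuron-like cells, which include clusters with motor neuron markers, in 6.76% (10.4% unthinned). Leukocyte-like cells, also outside the lineage, had one more often than neuron-like cells (shares given below). A reporter UMI alone therefore does not place a cell in the lineage.

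Neuronal, cell cycle and energy transcripts were lower in the older libraries. The motor neuron markers summed to 1893, 385 and 857 CPM at 3, 5 and 7 dpf, with 11 of 11 measured members lower at 7 than at 3 dpf. Inhibitory neuron markers summed to 397, 37.9 and 58.2 CPM and general neuron markers to 6050, 2062 and 3233 CPM. The markers of V2 and Kolmer-Agduhr interneurons summed to 565, 70.7 and 117 CPM. The G2/M list was at 857, 318 and 58.1 CPM, with 18 of 19 measured members lower at 7 dpf, and the S-phase list was at 662, 476 and 250 CPM. Nuclear-encoded oxidative phosphorylation genes summed to 4506, 2605 and 1898 CPM and glycolysis genes to 1719, 1054 and 1016 CPM. The Hedgehog list was at 389, 931 and 793 CPM, with gli1, a Hedgehog target and effector, 4.02-fold higher at 7 than at 3 dpf (3.45 to 4.70). The Notch list was at 1280, 1927 and 950 CPM, the Wnt list at 859, 1130 and 813, and the Fgf list at 1023, 949 and 819. Cholesterol biosynthesis genes were at 427, 271 and 250 CPM, glial matrix genes at 1083, 869 and 895, receptor and channel genes at 971, 456 and 776, trunk Hox genes at 3235, 2033 and 2299, and forebrain to midbrain-hindbrain boundary genes at 113, 218 and 91.8. The 10 myelin genes summed to 15870, 15579 and 12387 CPM.

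Transcripts of cells outside the lineage also differed between libraries. Dissociation stress genes summed to 932, 1503 and 1692 CPM at 3, 5 and 7 dpf, beside median mitochondrial shares of 0.693%, 0.95% and 1.28%. Erythroid markers were at 668, 6.08 and 4.79 CPM, skeletal muscle markers at 17.4, 316 and 51.7, and epidermal markers at 73.7, 360 and 714. Microglia and macrophage markers were at 24.9, 394 and 392 CPM and neutrophil markers at 3.73, 12.2 and 170. Lyz, a lysozyme gene of neutrophils, was 99.8-fold higher at 7 than at 3 dpf (62.0 to 172), from 17 and 999 UMIs. Over the 3 libraries, 967 lyz UMIs lay in leukocyte-like cells, of which 2.48% had one (unthinned). Markers of the retina (6.55, 8.64 and 5.50 CPM), the lens (0.747, 1.77 and 1.55) and excitatory neurons (14.8, 10.8 and 4.23) were low in all 3 libraries. Markers of liver, gut and pancreas were at 633, 363 and 300.3 CPM, of cerebellar neurons at 355, 113 and 80.5, of cartilage and notochord at 98.9, 183 and 113, of mural cells and fibroblasts at 184, 233 and 161, of pigment cells at 27.8, 39.6 and 83.9, of endothelium at 16.7, 6.67 and 58.4, and of hair cells at 28.5, 7.26 and 9.02. Progenitor and radial glia markers were at 3163, 5367 and 2170 CPM, ependymal and floor plate markers at 282, 569 and 349, OPC markers at 1421, 1324 and 1394, premyelinating markers at 1293, 1303 and 1293, myelinating markers at 15769, 15446 and 12283, and Schwann and neural crest markers at 1112, 1159 and 1158.

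Clustering gave 25 clusters, of which 22 were named. The OPC-like class was cluster 18, with sox10, olig2 and nkx2.2a at 880, 1697 and 664 CPM and leading genes that included tnr and bcan. Oligodendrocyte-like cells were clusters 2, 5 and 11, with mbpa at 7990, 485 and 12166 CPM. Progenitor-like cells were clusters 16, 20 and 22. Cluster 16 was led by dla and neurog1, cluster 20 by gfap and cx43 among others, and cluster 22 by zgc:158463, gli1 and ptch1, among others. Ependymal/floor-plate-like cells were cluster 3, and neuron-like cells 10 clusters. Schwann/neural-crest-like cells were clusters 8 and 15, of which cluster 8 was led also by cell cycle genes (aspm, ube2c, top2a). Leukocyte-like cells were cluster 23. Cluster 6 stayed unnamed, with hapln1b, s100b and etv1 among its leading genes. Thinned to 1000 UMIs, 91.5% of OPC-like cells had a reporter UMI (exact interval 87.2% to 94.6%; 95.4% unthinned), as had 82.9% of oligodendrocyte-like (80.7% to 85.0%; 89.8% unthinned) and 66.6% of progenitor-like cells (62.6% to 70.32%; 70.6% unthinned). The share was 6.76% in neuron-like cells (10.4% unthinned), 15.6% in Schwann/neural-crest-like cells (27.5%) and 37.6% in leukocyte-like cells (53.0%). Why leukocyte-like cells, which are outside the lineage, held reporter UMIs was not tested. The median depth was 4766 UMIs in OPC-like, 2829 in oligodendrocyte-like, 1855 in progenitor-like, 1561 in neuron-like, 3052 in Schwann/neural-crest-like and 6076 in leukocyte-like cells.

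**Figure D1:**
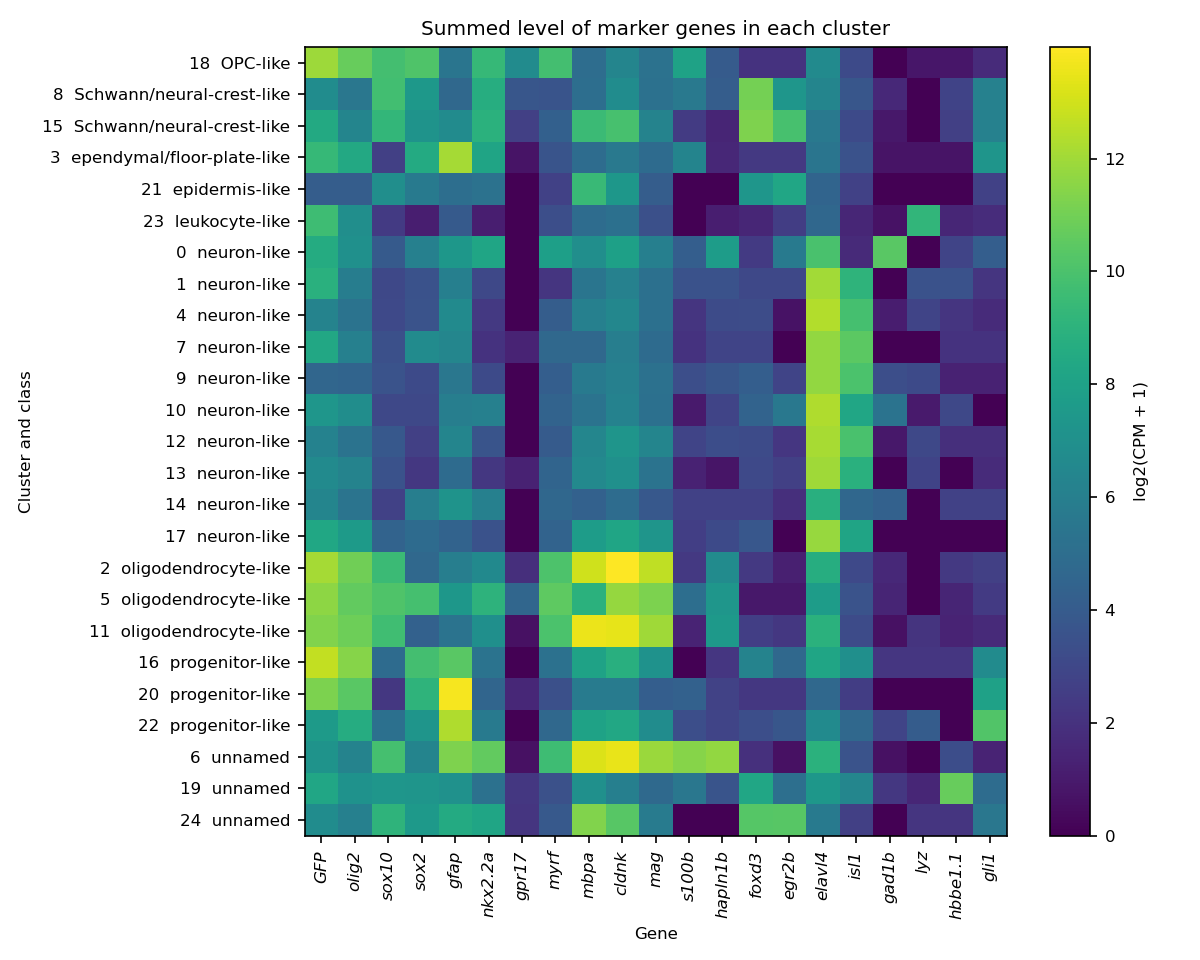
Summed level of 21 marker genes in each of the 25 clusters, as log2 of CPM plus 1 (colour), with the cluster number and class on the vertical axis. The reporter and olig2 are highest in clusters 2, 5, 11, 16, 18 and 20, but not in the progenitor-like cluster 22 (olig2 at 395 CPM), and cluster 6 combines mbpa and cldnk with olig2 at 75.0 CPM.

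Progenitor-like and oligodendrocyte-like cells made up larger shares of the older libraries. Progenitor-like cells were 2.50% of cells at 3 dpf (109 of 4367; exact interval 2.05% to 3.00%), 17.1% at 5 dpf (363 of 2118; 15.6% to 18.8%) and 12.2% at 7 dpf (219 of 1788; 10.8% to 13.9%), a 7 to 3 dpf ratio of 4.91 (3.93 to 6.13). Oligodendrocyte-like cells were 10.7% (466 cells; 9.77% to 11.6%), 23.8% (505; 22% to 25.7%) and 24.1% (431; 22.1% to 26.2%), a ratio of 2.26 (2.01 to 2.54). That ratio depends on leaving out cluster 6, which held 393, 137 and 30 cells at 3, 5 and 7 dpf. Its best list was the myelinating one, with 8 of 11 markers above 2-fold. It stayed unnamed because its 10 leading genes held 1 marker of another class and 0 of its own. Counted as oligodendrocyte-like, it would lower the ratio, by an amount that was not computed. OPC-like cells were 3.18% (139), 3.64% (77) and 2.52% (45), a ratio of 0.791 (0.568 to 1.1). That interval includes 1, but not with at least 1000 UMIs per cell (0.649, 0.465 to 0.904), at resolution 0.5 (0.730, 0.576 to 0.926) or over neural classes (0.714, 0.513 to 0.994). Neuron-like cells were 59.7% (2608), 23.9% (506) and 47.0% (840), a ratio of 0.787 (0.745 to 0.831), and ependymal/floor-plate-like cells 3.46% (151), 6.47% (137) and 2.24% (40), a ratio of 0.647 (0.459 to 0.913). Leukocyte-like cells were 0.275% (12), 5.71% (121) and 3.86% (69), epidermis-like cells 3, 3 and 10 in number, and 10.8%, 9.30% and 6.99% of cells stayed unnamed.

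Different clusters held most of a class at different ages. Clusters were made without batch integration, so a shift with age or library that split like cells cannot be told apart from a different make-up. Of progenitor-like cells, clusters 16, 20 and 22 held 53, 51 and 5 at 3 dpf, 40, 305 and 18 at 5 dpf, and 15, 48 and 156 at 7 dpf. Cluster 22 had a median mitochondrial share of 5.70%, the highest of the 25 clusters, and without it the progenitor-like ratio was 1.48. Of oligodendrocyte-like cells, clusters 2, 5 and 11 held 303, 142 and 21 at 3 dpf and 32, 39 and 360 at 7 dpf. Of neuron-like cells, cluster 13 held 8, 36 and 487, and cluster 12, which shares leading genes such as isl2b with it, 679, 201 and 56. Schwann/neural-crest-like cells were 9.32% (407), 9.87% (209) and 0.503% (9) of cells, a ratio of 0.0540 (0.0280 to 0.104). With the naming rule as first written, which gives this class cluster 24 (0, 1 and 71 cells), the ratio was 0.480. The size of the progenitor-like ratio depended on the clustering, from 1.42 with readout genes kept to 11.9 at resolution 0.5. The ependymal ratio turned to 2.22 at resolution 2.0 and to 2.88 with readout genes kept, and the neuron-like ratio to 1.08 with each library clustered alone.

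**Figure D2:**
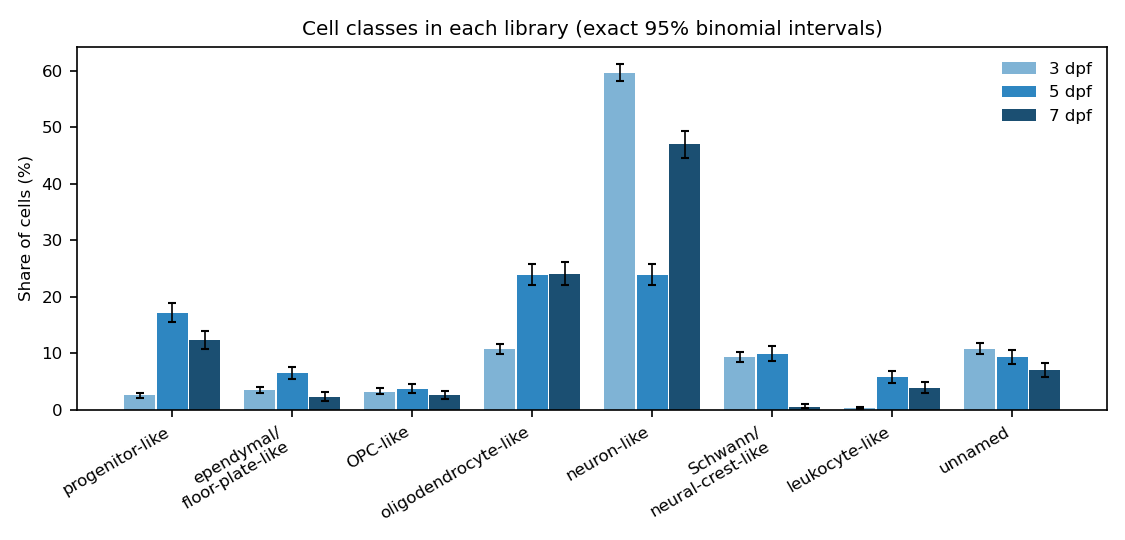
Share of cells (%) in each class at 3, 5 and 7 dpf, 1 library each, with exact 95% binomial intervals that cover counting error only. Oligodendrocyte-like cells, without the unnamed cluster 6, stand at 10.7%, 23.8% and 24.1%, and neuron-like cells at 59.7%, 23.9% and 47.0%.

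Within progenitor-like cells, Notch pathway transcripts were lower and Hedgehog pathway transcripts higher at 7 than at 3 dpf. Of 27 measured Notch genes 21 were lower, with a median log2 ratio of -1.41 (-1.70 to -1.22 over Poisson redraws; percentile 0 among 10000 matched random lists). The targets her4.1 and her15.1 were 7.67-fold (5.81 to 10.2) and 5.07-fold (3.94 to 6.58) lower, and the ligand genes dlb and dla 26.7-fold (15.5 to 49.9) and 4.90-fold (4.19 to 5.75) lower. Cluster 16, with dla, dlc, dlb and lfng among its leading genes, held 53 of 109 cells of the class at 3 dpf and 15 of 219 at 7 dpf, so the ratios of these genes also read the make-up of the class. Without that cluster the Notch median was -1.29 (-1.56 to -0.83; percentile 0). Of 15 Hedgehog genes 12 were higher, with a median of 0.79 (0.36 to 1.58; percentile 98.7). Gli1 was 3.94-fold (2.93 to 5.41) and ptch1 3.77-fold (2.86 to 5.04) higher, while gli2a and gli3 had ratios of 0.977 (0.725 to 1.33) and 0.967 (0.710 to 1.33). Dissociation stress genes had a median of 1.15 (percentile 99.6), with 8 of 10 higher, among them socs3a at 42.7-fold from 1 UMI at 3 dpf (7.48 to 1704). Oxidative phosphorylation genes had a median of -1.48 (percentile 0.165), with 15 of 17 lower, among them atp5mc1, a subunit of ATP synthase, 11.7-fold (6.28 to 23.9). DNA replication genes had a median of -1.89 (percentile 0.02), with 10 of 12 lower, from counts of at most 20 UMIs at 3 dpf, and turned to 1.54 at resolution 2.0 and to 0.28 (-0.51 to 2.56) without cluster 16. Percentiles were 66.1 for Wnt, 80.0 for Fgf, 16.3 for cholesterol biosynthesis, 46.8 for glycolysis, 30.2 for glial matrix, 81.8 for receptors and channels, and 15.6 for trunk Hox genes. The Hedgehog median was 0.22 with cells thinned before summing (percentile 88.7), 0.47 without cluster 22 (94.8), 0.65 with each library clustered alone (96.6) and 1.26 without cluster 16 (99.96), so in the first 3 of these settings the list did not stand apart from 95% of random lists. Nor did the stress list with each library clustered alone (0.54, percentile 92.6), with doublets kept (0.82, 97.0) or with thinned cells (1.64, 97.49), the oxidative phosphorylation list without cluster 22 (-0.82, percentile 5.94) or with readout genes kept in clustering (-0.91, 4.15), or the DNA replication list with doublets kept (-0.12, 52.0), with readout genes kept (-0.80, 11.2), without cluster 22 (-0.99, 4.44) and in the 2 settings that turned its sign (94.6 and 64.3). TMM scaling would move all log2 ratios in this class by 0.31. With it the medians were -1.11 for Notch, 1.1 for Hedgehog, 1.45 for stress, -1.18 for oxidative phosphorylation and -1.63 for DNA replication genes, while a shift of that size would turn the Wnt and glycolysis medians (-0.004 and -0.216) above 0.

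Single genes of progenitor-like cells differed by larger folds. The gene zgc:158463 was at 290 CPM at 3 dpf, 1968 at 5 dpf and 89630 at 7 dpf, 309-fold higher (249 to 388). The prostaglandin D synthase genes ptgdsb.1 and ptgdsb.2 were at least 285-fold and 194-fold (53.7 to 1608) higher, wu:fi09b08 255-fold (70.6 to 2112), AL935186.10 167-fold (56.9 to 810), BX548011.2 at least 62.1-fold, the transcription factor gene cebpd 112-fold (38.3 to 546), and the metalloproteinase inhibitor gene timp4.3 at least 41.6-fold. Lower were hapln1a, a hyaluronan link protein gene, by at least 65.3-fold, ccndx by at least 41.8-fold, si:ch73-21g5.7 by at least 35.2-fold, the retinoic acid binding protein gene crabp1b by 49.9-fold (25.8 to 111), abhd6a by 44.7-fold (23.8 to 94.6), marcksb by 37.7-fold (19.3 to 84.0), the midkine gene mdka by 29.5-fold (24.3 to 36.2), and mid1ip1b by 106-fold from 1 UMI at 7 dpf (18.1 to 4260). The genes zgc:158463, wu:fi09b08, AL935186.10 and BX548011.2 led cluster 22, ptgdsb.1 and ptgdsb.2 were leading genes of cluster 20, and abhd6a of cluster 16, so these ratios also read which cluster held the class at each age. Without cluster 16 the ratio of abhd6a was 0.168. Some of the lower genes were leading genes of other classes: mid1ip1b of the oligodendrocyte-like cluster 2, crabp1b of the neuron-like clusters 9 and 12, and mdka of the ependymal/floor-plate-like cluster 3. Olig2 had a ratio of 0.578 (0.519 to 0.645), sox2 of 0.502 (0.408 to 0.616), mbpa of 0.662 (0.486 to 0.907), sox10 of 1.21 (0.450 to 3.78) and the reporter of 0.242 (0.223 to 0.262).

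Within oligodendrocyte-like cells, cholesterol biosynthesis genes were lower at 7 than at 3 dpf in 15 of 15 measured members. The median log2 ratio was -1.56 (-2.34 to -1.44; percentile 0). Clusters 2 and 5 held 303 and 142 of the 466 cells at 3 dpf, and cluster 11 held 360 of 431 at 7 dpf. The ratios in this class thus also read which cluster held it at each age, and no setting compared the ages within 1 of these clusters. Whether the clusters are different kinds of cells or like cells split by an age or library shift cannot be told apart here. Hmgcra, the rate-limiting reductase of the pathway, had 48 UMIs at 3 dpf and none at 7 dpf, at least 14.8-fold lower. Mvda was 34-fold lower from 3 UMIs (11.3 to 167), hmgcs1 5.68-fold (3.27 to 10.6) and fdps 2.98-fold (2.32 to 3.87), while insig1, a regulator of the pathway, had a ratio of 0.867 (0.746 to 1.01). Oxidative phosphorylation genes had a median of -1.16 (percentile 0.01) with 15 of 17 lower, among them cytochrome c gene cycsb 13.3-fold (8.93 to 20.6). Sdha went the other way, 2.39-fold higher (1.79 to 3.22). Percentiles were 85.8 for Notch, 89.5 for Hedgehog, 68.8 for Wnt, 88.3 for Fgf, 82.7 for S-phase, 88.3 for stress, 41.8 for glycolysis, 14.3 for glial matrix, 85.8 for receptors and channels, and 59.4 for trunk Hox genes. TMM scaling would move all log2 ratios in this class by -0.34. With it the medians were -2.28 for cholesterol biosynthesis and -1.49 for oxidative phosphorylation genes, while a shift of that size would turn the glycolysis median (0.247) below 0. The cholesterol median was -2.18 with each library clustered alone.

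Single genes of oligodendrocyte-like cells differed by larger folds. Ddit4, an inhibitor of mTORC1 signalling, was at 3.88 CPM at 3 dpf, 87.0 at 5 dpf and 1293 at 7 dpf, 333-fold higher (162 to 830). Lpin1, a phosphatidate phosphatase, was 63.0-fold (46.3 to 88.0), gstr, a glutathione S-transferase, 60.8-fold (37.2 to 107), zgc:158463 38.1-fold (35.1 to 41.5; at 12109 CPM at 7 dpf, beside 8888 in neuron-like, 10319 in OPC-like and 89630 in progenitor-like cells), si:dkey-205h13.1 42.2-fold (30.2 to 60.9) and wu:fi09b08 92.1-fold higher from 3 UMIs (31.2 to 450). At 7 dpf wu:fi09b08 was at 153 CPM in this class, beside 146 in neuron-like and 1786 in progenitor-like cells. The mineralocorticoid receptor gene nr3c2 and cebpa were at least 39.9-fold and 37.1-fold higher. Lower were abracl by 64.4-fold from 2 UMIs at 7 dpf (17.5 to 537), the endoplasmic reticulum stress factor gene manf by 24.9-fold (16.7 to 38.7), dnajb11, a chaperone of that compartment, by 22.4-fold (12.6 to 43.8), uchl3 by 22.1-fold (14.4 to 35.6), CABZ01085139.1 by 19.9-fold (10.3 to 44.1), chd4a by 17.1-fold (9.62 to 33.7) and mid1ip1b by 10.8-fold (9.64 to 12.2). Olig2 and sox10 had ratios of 0.997 (0.951 to 1.05) and 0.935 (0.872 to 1.00), mbpa of 1.43 (1.40 to 1.47), sox2 of 0.503 (0.433 to 0.583) and the reporter of 0.474 (0.456 to 0.493). Clusters 2 and 5 held most of this class at 3 dpf and cluster 11 at 7 dpf, so these ratios also read which cluster held the class at each age.

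Within neuron-like cells, glycolysis and oxidative phosphorylation genes were both lower at 7 dpf. Glycolysis had a median log2 ratio of -1.27 (-1.57 to -1.12; percentile 0), with 14 of 15 lower, among them eno1a 9.02-fold (6.79 to 12.2) and gapdhs 7.54-fold (6.62 to 8.62). Oxidative phosphorylation had a median of -1.45 (-1.53 to -1.24; percentile 0), with 15 of 17 lower. Glial matrix genes had a median of -1.04 (percentile 1.65), with 6 of 6 lower, and trunk Hox genes of -0.62 (percentile 1.22). With each library clustered alone these medians were -0.53 (percentile 13.4) and -0.39 (percentile 9.27), no longer apart from 95% of random lists. The glial matrix list was also just inside with doublets kept (percentile 2.66) and at resolution 0.5 (2.71), and the trunk Hox list with at least 1000 UMIs per cell (2.9). Hoxb8a and hoxb5b were 5.32-fold (4.11 to 7.01) and 5.66-fold (3.83 to 8.71) lower, whereas hoxc6b was 2.03-fold higher (1.69 to 2.45) and hoxd3a had a ratio of 1.01 (0.95 to 1.08). Percentiles were 3.03 for Notch, 87.1 for Hedgehog, 22.3 for Wnt, 21.7 for Fgf, 53.6 for cholesterol biosynthesis, 62.4 for S-phase, 91.0 for stress, and 41.2 for receptors and channels. Cluster 13 held 487 of the 840 neuron-like cells at 7 dpf, so these ratios also read which cluster held the class at each age. TMM scaling would move all log2 ratios in this class by -0.13, a shift that would turn the cholesterol biosynthesis median (0.065) below 0.

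**Figure D3:**
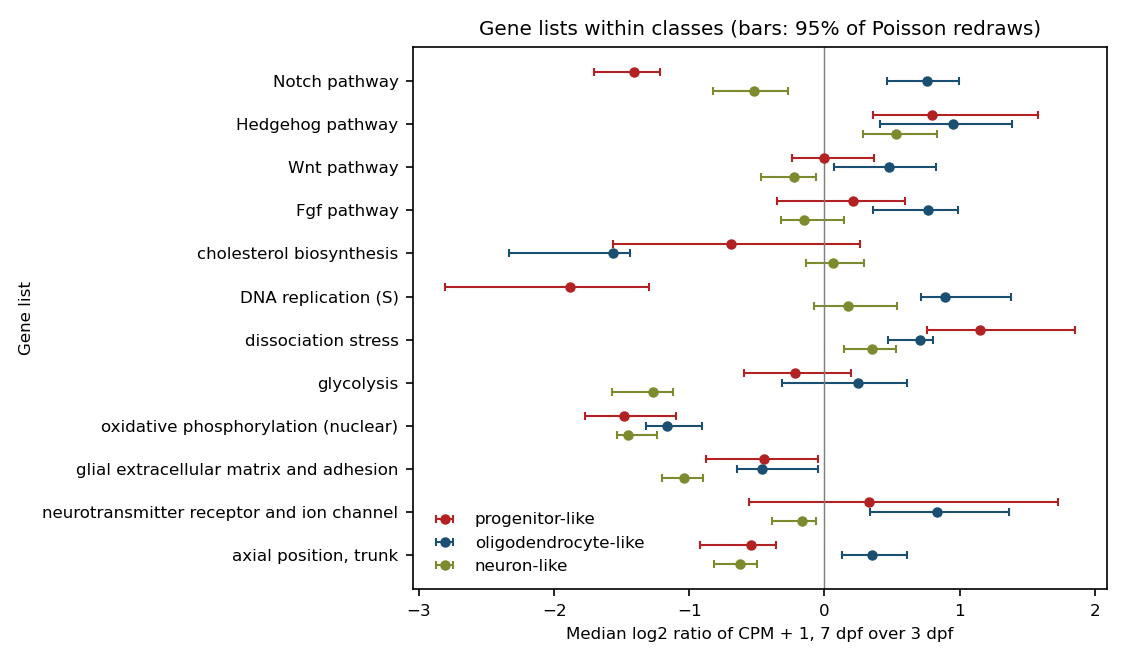
Median log2 ratio of CPM plus 1 (7 over 3 dpf) of each readout list in progenitor-like, oligodendrocyte-like and neuron-like cells, with bars over 95% of Poisson redraws. Oxidative phosphorylation lies at -1.48, -1.16 and -1.45, and cholesterol biosynthesis at -1.56 in oligodendrocyte-like cells.

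Proliferating cells were found among Schwann/neural-crest-like, OPC-like and unnamed cells at 3 dpf. Thinned, 16 of 133 OPC-like cells (12%, exact interval 7.03% to 18.8%) had at least 2 UMIs of the G2/M list at 3 dpf, 5 of 71 (7.04%, 2.33% to 15.7%) at 5 dpf, and 0 of 42 at 7 dpf, which allows a share of up to 7.14%. Unthinned shares were 21.6%, 9.09% and 4.44%. A difference between 5 and 7 dpf was not detectable at this number of cells. Of Schwann/neural-crest-like cells, 82 of 384 (21.4%, 17.4% to 25.8%) were positive at 3 dpf, when cluster 8 held 251 of 407 cells of the class, and 5 of 191 (2.62%, 0.855% to 6.0%) at 5 dpf, when cluster 15 held 191 of 209 (29.2% and 2.87% unthinned). At 7 dpf 0 of 7 were positive, which excludes little. Of unnamed cells, most of them in cluster 6 at 3 and 5 dpf, 30 of 455 (6.59%, 4.49% to 9.28%) were positive at 3 dpf, 9 of 176 (5.11%, 2.36% to 9.49%) at 5 dpf and 0 of 115 (up to 2.61%) at 7 dpf (12.1%, 9.14% and 8% unthinned). Ependymal/floor-plate-like cells were at 2.96% (0.813% to 7.41%), 3.97% (1.3% to 9.02%) and 0 of 39 (up to 7.69%), with 4.64%, 6.57% and 0% unthinned. Progenitor-like cells were at 0 of 99 (up to 3.03%), 7 of 319 (2.19%) and 0 of 183 (up to 1.64%), with 2.75%, 2.2% and 0.913% unthinned. The background in neuron-like cells, which do not divide, was 0.389%, 0 of 220 (up to 1.36%) and 0.700% (0.805%, 0.198% and 2.38% unthinned). Oligodendrocyte-like cells had 0.451%, 0 of 396 (up to 0.758%) and 1.01%, with intervals that overlap those of that background. Unthinned, at a greater depth than neuron-like cells, they lay above it at 3 dpf (3.86%, 2.31% to 6.04%, against 0.499% to 1.23%) and 7 dpf (9.74%, 7.11% to 12.9%, against 1.46% to 3.65%), but not at 5 dpf (0.396%). Only 2 of 26 G2/M rows reached a mean of 10 CPM over 3 and 7 dpf in oligodendrocyte-like cells. Which genes gave these UMIs, and whether such cells divide, was not tested. The 3 dpf values moved with the clustering, to 6.42% for OPC-like cells at resolution 0.5 and to 4.38% for Schwann/neural-crest-like cells with readout genes kept.

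**Figure D4:**
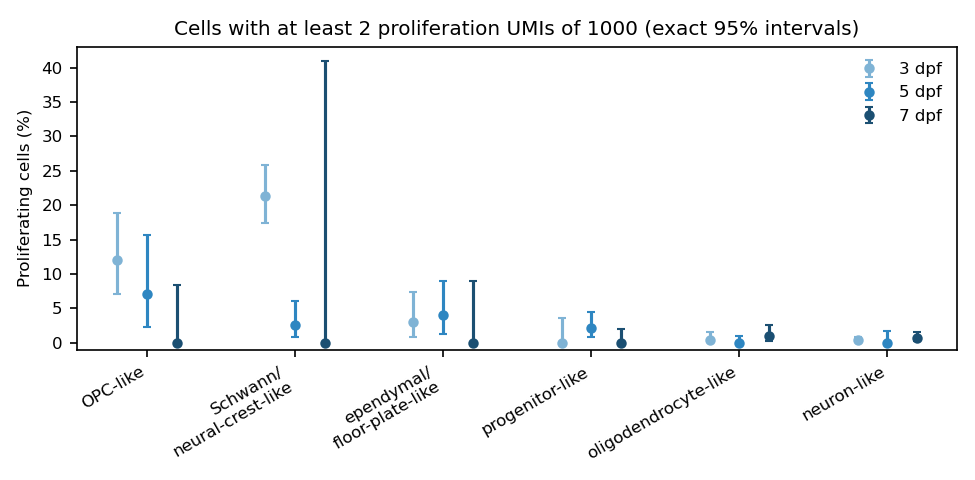
Share of cells (%) with at least 2 UMIs of the G2/M list after thinning to 1000 UMIs, by class and age, with exact 95% binomial intervals that cover counting error only. OPC-like cells stand at 12%, 7.04% and 0 of 42 cells, and Schwann/neural-crest-like cells at 21.4% and 2.62% at 3 and 5 dpf.

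The contrast of oligodendrocyte-like with OPC-like cells asked which pathways separate differentiating and differentiated cells from their precursors within the same libraries. The oligodendrocyte-like sums include cluster 5, named from the premyelinating list, at 30.5%, 15.0% and 9.05% of the class at 3, 5 and 7 dpf. Their make-up thus differs between the libraries. Cell cycle genes fell in oligodendrocyte-like cells: 12 of 15 tested G2/M genes and 11 of 16 S-phase genes were lower by edgeR's quasi-likelihood test (12 and 12 adjusted over the list alone), and 1 of each list was higher. Nusap1 had a log2 fold of -5.89 (SE 0.85, adjusted p = 4.84e-05) and aspm of -6.70 (SE 0.86, adjusted p = 1.38e-05), while gmnn, a replication licensing inhibitor, rose by 1.76 (SE 0.31, adjusted p = 0.000299). Dissociation stress genes rose in 5 of 11 (6 over the list alone), among them jun by 6.08 (SE 0.46, adjusted p = 7.22e-08) and klf6a by 4.97 (SE 0.43, adjusted p = 2.34e-07). Cholesterol genes rose in 4 of 11 (4 over the list alone), among them insig1 by 2.17 (SE 0.31, adjusted p = 4.02e-05). Receptor and channel genes fell in 6 of 12 (6 over the list alone). The AMPA receptor gene gria1a had a log2 fold of -5.17 (SE 0.50, adjusted p = 6.06e-07), and gria2b was at 13.6, 16.2 and 112 CPM in the OPC-like sums with no UMI in the oligodendrocyte-like sums. Fgf genes fell in 6 of 12 (6 over the list alone), with fgfr3 at -5.12 (SE 0.63, adjusted p = 9.41e-06), although fgfr1a rose by 3.66 (SE 0.35, adjusted p = 5.55e-07). All genes given here with a log2 fold, apart from nusap1, had that sign in 3 of 3 libraries, and nusap1 in 2.

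Other lists moved in few members or both ways. Glial matrix genes split into 3 higher and 3 lower of 10 (3 and 3 over the list alone). Nfasca, a neurofascin gene, rose by 6.34 (SE 0.51, adjusted p = 1.09e-07), and the tenascin R gene tnr had a log2 fold of -4.79 (SE 0.51, adjusted p = 1.91e-06). Of Notch genes 2 rose and 4 fell of 24 (2 and 4 over the list alone), with jag2b at 4.02 (SE 0.54, adjusted p = 2.44e-05) and lfng at -3.13 (SE 0.43, adjusted p = 3.02e-05). Of Hedgehog genes 1 rose and 2 fell of 15, of Wnt genes 3 fell of 11 (1 rose and 4 fell over the list alone), of glycolysis genes 2 rose and 1 fell of 15, of oxidative phosphorylation genes 2 fell of 17, of trunk Hox genes 3 rose and 1 fell of 19, and of the forebrain list 1 fell of 2; the other counts over the list alone were equal to these. The lineage genes olig2 and sox10 and the reporter (GFP) had log2 folds of 0.17 (SE 0.29, adjusted p = 0.718), -0.07 (SE 0.36, adjusted p = 0.920) and -0.09 (SE 0.30, adjusted p = 0.860). In all, 75 of 190 readout genes passed, 23 higher and 52 lower, among 2830 of 10237 genes. Without the 3 dpf library the count was 43 and without the 5 dpf library 44, without the library block 43 (14 higher, 29 lower), and with cells thinned before summing 32 (14 higher, 18 lower). With the preset correlation camera called 6 lists (G2/M and S-phase adjusted p = 0.00219 each; stress, cholesterol, oxidative phosphorylation and receptors adjusted p = 0.0281 each). With an estimated correlation none passed (adjusted p = 0.504 for each of these 6).

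The contrast of progenitor-like with OPC-like cells asked which pathways mark the step into the oligodendrocyte lineage. Notch and Hedgehog genes were higher in progenitor-like cells: 20 of 24 tested Notch genes (21 adjusted over the list alone, with 1 lower) and 11 of 15 Hedgehog genes (12 over the list alone) rose by edgeR's quasi-likelihood test. Among Notch genes, dla rose by 3.89 (SE 0.54, adjusted p = 2.32e-05), and the target genes her15.1 and hey1 were at 680, 384 and 153 CPM and at 289, 474 and 153 CPM in the progenitor-like sums against at most 16.7 CPM in any OPC-like sum. Among Hedgehog genes, the inhibitor gene hhip rose by 7.06 (SE 0.53, adjusted p = 4.66e-08), ptch1 by 4.44 (SE 0.39, adjusted p = 1.86e-07) and gli3 by 6.39 (SE 0.58, adjusted p = 2.44e-07). Trunk Hox genes rose in 14 of 19 (15 over the list alone, with 1 lower), with hoxb3a at 2.95 (SE 0.32, adjusted p = 1.43e-06). Both tested genes of the forebrain list rose, with pax6a, also a ventral spinal progenitor gene, at 6.37 (SE 0.49, adjusted p = 6.13e-08). Stress genes rose in 7 and fell in 1 of 11 (8 and 1 over the list alone), with jun at 3.41 (SE 0.47, adjusted p = 1.86e-05), and glycolysis genes rose in 6 of 15 (6 over the list alone), with aldocb at 3.87 (SE 0.45, adjusted p = 2.99e-06). All genes given here with a log2 fold had that sign in 3 of 3 libraries.

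Of the readout genes lower in progenitor-like than in OPC-like cells, most belonged to the G2/M, oxidative phosphorylation and receptor lists. G2/M genes fell in 9 of 15 (12 over the list alone), with ube2c at -2.47 (SE 0.64, adjusted p = 0.00628, that sign in 2 of 3 libraries), and S-phase genes in 2 of 16 (0 over the list alone). Oxidative phosphorylation genes fell in 8 of 17 (8 over the list alone), with atp5mc1 at -2.28 (SE 0.37, adjusted p = 9.33e-05). Receptor and channel genes fell in 6 and rose in 1 of 12 (6 and 1 over the list alone), with gria1a at -3.44 (SE 0.50, adjusted p = 3.48e-05). Glial matrix genes rose in 5 and fell in 3 of 10 (5 and 3 over the list alone). Tnr had a log2 fold of -8.02 (SE 0.65, adjusted p = 8.89e-08) and vcanb, a versican gene, of -5.94 (SE 0.47, adjusted p = 6.97e-08), while ptprz1a was at 375, 252 and 324 CPM against 0, 0 and 6.80. Wnt genes rose in 4 and fell in 3 of 11 (4 and 3 over the list alone), Fgf genes rose in 4 and fell in 2 of 12 (4 and 2 over the list alone), and 1 of 11 cholesterol genes rose (0 over the list alone), a list whose median of 0.03 and camera direction (down) differ in sign. The lineage gene olig2 and the reporter (GFP) had log2 folds of -0.06 (SE 0.29, adjusted p = 0.896) and -0.17 (SE 0.30, adjusted p = 0.723). In all, 109 of 190 readout genes passed, 75 higher and 34 lower, among 3339 of 10237 genes, and without the 5 dpf library the count was 60 (53 higher, 7 lower). The lower calls were also few without the library block (60 higher, 9 lower) and with cells thinned before summing (53 higher, 8 lower). With the preset correlation camera called 7 lists: Notch (adjusted p = 1.00e-15), Hedgehog (3.16e-09), trunk Hox (2.75e-06), G2/M (0.00231), oxidative phosphorylation (0.00469), stress and receptors (0.0383 each), but not S-phase (0.0833). With an estimated correlation Hedgehog alone passed (adjusted p = 0.0345). The adjusted p was then 0.240 for Notch, trunk Hox, oxidative phosphorylation and stress, and 0.524 for G2/M and receptors. The estimated correlation was negative for Hedgehog (-0.063), against 0.407 for Notch and 0.664 for G2/M. These estimates come from few sums, so the pass of Hedgehog alone does not set it apart from the other lists.

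**Figure D5:**
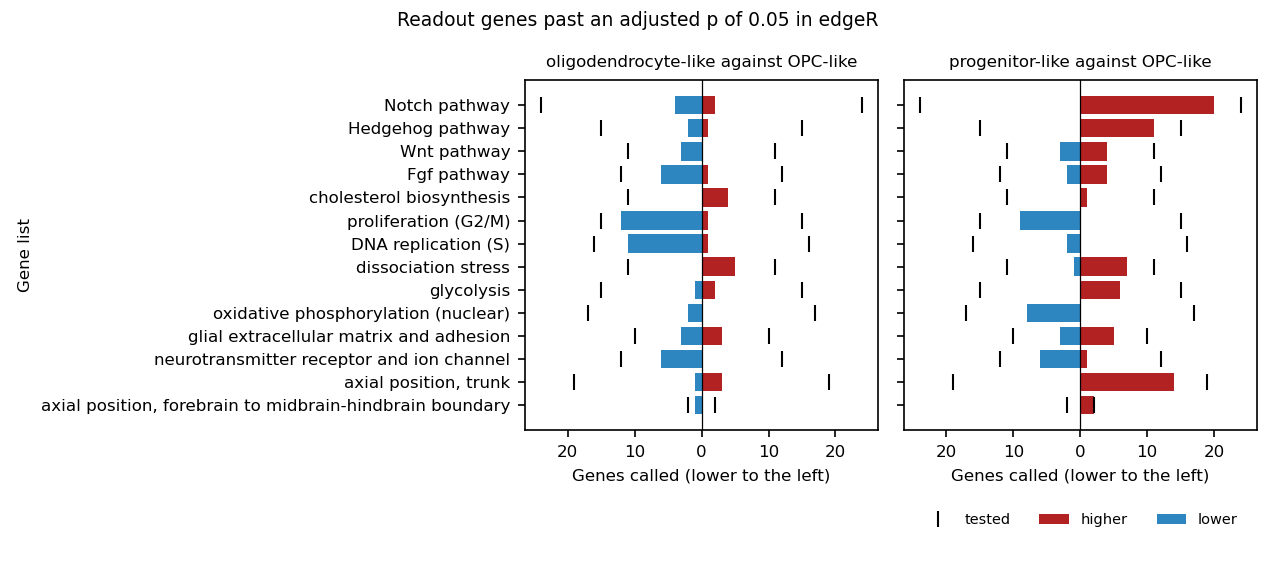
Number of genes of each readout list called higher (right) or lower (left) at an adjusted p of 0.05 in edgeR, with ticks at the number tested, in both class contrasts. The bars for progenitor-like cells reach 20 of 24 Notch genes and 11 of 15 Hedgehog genes.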

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

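Age and library were the same variable, so no alternative separates them, and the p-values of the class contrasts measure only the spread between these 9 sums. The expected doublets removed, the naming rule as first written and the omission of cluster 22 or of cluster 16 were alternatives chosen after seeing the data. Of the ratios of class shares, 35 stayed within their counting interval, 16 moved and 3 reversed. The progenitor-like ratio of 4.91 was 8.22 with at least 1000 UMIs, 3.64 with at most 10% mitochondrial UMIs, 8.51 with doublets kept, 11.9 at resolution 0.5, 3.07 at resolution 2.0, 1.42 with readout genes kept and 1.93 with each library alone. Without cluster 22 it was 1.48, which is not in the count above, since that setting removes cells of the class by construction. The ependymal ratio of 0.647 reversed to 2.22 at resolution 2.0 and to 2.88 with readout genes kept. The OPC-like ratio of 0.791 had an interval that includes 1, but not with at least 1000 UMIs (0.649), at resolution 0.5 (0.730) or over neural classes (0.714). The oligodendrocyte-like ratio of 2.26 was 2.95 at resolution 0.5 and 2.87 with each library alone. It would be lower with the unnamed cluster 6 counted in the class, a ratio that was not computed. The neuron-like ratio of 0.787 reversed to 1.08 with each library alone and was 0.710 over neural classes. The Schwann/neural-crest-like ratio of 0.0540 was 0.496 with at most 10% mitochondrial UMIs, 0.478 with doublets kept, 0.480 at resolution 0.5, 0.573 with readout genes kept, 0.0222 with the expected doublets removed and 0.480 with the naming rule as first written. The cause was not tested.

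Of the list medians within classes, 98 stayed within their interval, 21 moved and 2 reversed. In progenitor-like cells the Notch median of -1.41 was -1.04 with readout genes kept, -1.11 with TMM sizes and -1.80 with thinned cells, and the Hedgehog median of 0.79 was 0.22 with thinned cells. Without cluster 16 these were -1.29 and 1.26, within their intervals. The DNA replication median of -1.89 reversed to 1.54 at resolution 2.0 and to 0.28 without cluster 16, and was -0.12 with doublets kept, -0.80 with readout genes kept, -2.95 with each library alone, -0.99 without cluster 22 and -3.34 with thinned cells. The stress median of 1.15 was 0.54 with each library alone, and the oxidative phosphorylation median of -1.48 was -0.91 with readout genes kept and -0.82 without cluster 22. In oligodendrocyte-like cells the oxidative phosphorylation median of -1.16 was -0.88 with each library alone and -1.49 with TMM sizes. In neuron-like cells it was -1.45, and -1.60, -1.58 and -1.23 with each library alone, TMM sizes and thinned cells. The glial matrix median there, -1.04, was -0.89 with doublets kept, -0.86 at resolution 0.5 and -0.53 with each library alone, and the trunk Hox median, -0.62, was -0.39 with each library alone. These lists stood apart from 95% of random lists, but did not in 3 settings for Hedgehog, 5 for DNA replication, 3 for stress and 2 for oxidative phosphorylation in progenitor-like cells, and in 3 for glial matrix and 2 for trunk Hox in neuron-like cells. Ratios of single named genes stayed within their interval in 277 cases and moved in 71. The cause was not tested.

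Of the proliferating shares, 37 stayed within their interval and 8 moved. The OPC-like share at 3 dpf, 12%, was 6.42% at resolution 0.5 and 21.6% unthinned. The Schwann/neural-crest-like share at 3 dpf, 21.4%, was 33.8% at resolution 2.0, 4.38% with readout genes kept, 28.9% with each library alone, 27.3% with the expected doublets removed, 29.2% unthinned and 28.6% from 1 UMI. Thinning removes UMIs and a minimum of 1 UMI admits more cells by construction; for the others the cause was not tested.

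In the contrast of oligodendrocyte-like with OPC-like cells, the 75 readout genes called (23 higher, 52 lower) were 43 without the library block (14 and 29), 43 to 69 with 1 library left out (43 without 3 dpf, 14 and 29; 44 without 5 dpf, 16 and 28) and 32 with thinned cells (14 and 18). In the contrast of progenitor-like with OPC-like cells, the 109 genes (75 higher, 34 lower) were 69 without the block (60 and 9), 60 to 97 with 1 library left out (60 without 5 dpf, 53 and 7) and 61 with thinned cells (53 and 8). Left-out libraries and thinning leave fewer sums or counts. With an estimated correlation camera called 0 of the 6 lists and 1 of the 7. The other settings, DESeq2 among them (70 and 96 genes), stayed within 1.5 times the count. Named genes kept their side of the threshold in 468 and 528 cases, lost it in 32 and 43, and passed it in 13 and 6. In library levels without mitochondrial, ribosomal protein and erythroid genes, ratios of 7 to 3 dpf were 0.866 for sox10, 1.56 for olig2, 1.43 for mbpa, 0.907 for sox2 and 0.822 for the reporter, and those of cldnk and spry2 reversed to 1.00 and 1.01; 717 other values stayed within their interval and 99 moved. A class that was not found in a setting at both ages, or with under 50 cells at 3 or 7 dpf for list medians, has no value there. Few simulated log2 changes of 1 were recovered, but with few changed genes the adjusted threshold was stricter there than in the real contrasts. What limits the contrasts was not tested.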

Other observations

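The tests of free RNA by the lpin1 ratio, and of doublets and free RNA for cluster 6, were chosen after their results were seen, as were the OPC-like age values and the neuron clusters below.

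OPC-like cells had only 45 cells at 7 dpf, under the minimum set for age ratios, so their values stand here. Receptor and channel genes were higher at 7 than at 3 dpf in 13 of 13 measured members, with a median log2 ratio of 2.69 (1.89 to 3.07; percentile 100 among matched random lists). Gria4a, an AMPA receptor gene, was 3.69-fold higher (3.04 to 4.49), gria2b 10.3-fold (4.80 to 24.4) and gria3b 13.6-fold (6.28 to 33.8). G2/M genes had a median of -5.15 with 19 of 19 lower, S-phase genes of -2.61 (15 of 17 lower), Hedgehog genes of 1.85 (7 of 7 higher; percentile 97.8) and Fgf genes of 1.64 (9 of 10 higher; percentile 98.9). Oxidative phosphorylation genes had a median of -1.20 (16 of 17 lower; percentile 0.21) and cholesterol biosynthesis genes of -0.93 (5 of 7 lower; percentile 1.08). TMM scaling would move these log2 ratios by -0.62, which turns the sign of none of the medians given here.

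Several neuron-like clusters differed in number of cells between the libraries. Cluster 0, led by urp1 and also by pkd2l1, a channel gene of cerebrospinal fluid-contacting neurons, had 135, 5 and 7 cells at 3, 5 and 7 dpf. Cluster 14, with the serotonergic genes tph2 and fev, had 109, 0 and 0 cells, and cluster 17, with vipb, phox2bb and hand2, had 50, 22 and 1 (1.14%, 1.04% and 0.0559% of cells). Cluster 13, with isl2b and sox11a, had 8, 36 and 487. Cluster 12, which shares the leading genes isl2b, onecut1, tshz3b and pou2f2a with cluster 13, had 679, 201 and 56. Without batch integration, a single population split by age or library cannot be told apart from separate ones. The mCherry row had 0 UMIs in the 3 libraries.

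Ddit4, lpin1, klf9, cebpd and zgc:158463 were higher at 7 than at 3 dpf in oligodendrocyte-like, progenitor-like and neuron-like cells, with a median log2 ratio of 5.25, although ddit4 and lpin1 were only 3.05-fold and 3.40-fold higher in neuron-like cells. These genes were picked from those most higher at 7 dpf in single classes of these data, so a high median followed from the choice. Against 1 common pool of free RNA as the whole cause for both genes, the ratio of lpin1 to zgc:158463 UMIs at 7 dpf differed 9.94-fold between the 7 classes with at least 20 lpin1 UMIs, from 0.0173 (0.0155 to 0.0193) in neuron-like to 0.172 in Schwann/neural-crest-like cells, of which there were 9; in 431 oligodendrocyte-like cells it was 0.118 (0.113 to 0.123). For zgc:158463 alone, at 8888 to 16307 CPM in 6 of these classes, free RNA stays open. It stays open too for wu:fi09b08, at 153 CPM in oligodendrocyte-like and 146 in neuron-like cells at 7 dpf. Against damaged cells as the whole cause for these picked genes, the median was 5.23 in cells with at most 1% mitochondrial UMIs. Thinning gave 5.23 as well but decides nothing on depth, since it scales the genes of a cell alike. Age, feeding state and the handling of the 7 dpf library remain open and cannot be told apart in this design.

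Cluster 6 (393, 137 and 30 cells) had sox10 at 935 CPM, mbpa at 9790 and cldnk at 11617, with olig2 at 75.0 and the reporter at 142 CPM. For doublets with an oligodendrocyte, olig2 was at 0.0407 of its level in oligodendrocyte-like cells (0.0341 to 0.0483). For free RNA as the source, cldnk was 101-fold its level in neuron-like cells (94.3 to 108). The cluster was singled out by its myelin transcripts and little olig2. Both values thus restate those traits and are no independent test of doublets or free RNA. Myelinating cells that express little olig2 may be a hypothesis for this cluster; their identity and position were not tested.

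The Hedgehog median in progenitor-like cells was 0.79. Without cluster 22 it was 0.47 (0.20 to 0.73; 104 and 63 cells), and in cells with at most 2% mitochondrial UMIs 0.70 (0.25 to 1.14; 96 and 46 cells). Both intervals include 0.40, the bound set for these tests, so neither the make-up of the class nor damaged cells can be told apart from a difference with age, which stays untested.

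The 6 sums of a contrast make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 75 readout genes for oligodendrocyte-like and 109 for progenitor-like against OPC-like cells, 1 of 10 splits with as many in each contrast, and the highest other split called 0. The other splits mix sums of both classes within a group, so the class difference adds to their spread. Their calls are therefore no measure of the real count.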
